A study of Vaccinium virgatum with 9 samples.

How the data were processed

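RNA was sequenced from fruit of rabbiteye blueberry (Vaccinium virgatum), a polyploid blueberry species, in 9 libraries. Potted plants received water, potassium sulfate at the flowering stage, or potassium sulfate at the young fruit stage, with 10 g of the fertilizer per plant in both potassium groups. Per the labels' protocols, fruit was picked 90 days after flowering, each replicate pooled 12 to 18 fruits, RNA was extracted by the Trizol method, and libraries were made with an NEBNext Ultra RNA kit. Each group held 3 libraries, and the group and the replicate number of every library were read from its title. The labels do not say whether the 3 replicates of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

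The deposited table holds whole-number counts per gene, 1 column per library, without normalization. The submitters' processing notes name HISAT2 2.1.0 (a read aligner) and StringTie 1.3.4d (a transcript assembler) without giving their roles, and the counting tool, the genome build, the annotation and the strand setting are not given in the sources used here. Counts made by way of a transcript assembler can be estimates rounded to whole numbers, and reads from near-identical gene copies of a polyploid can be split or merged by the counting; neither can be read from the table. All 38665 entries carry a gene identifier, and none is a total or an unassigned class. Of these, 28300 identifiers begin with Vadar and are called Vadar genes here, and the other 10365 share another prefix and are called non-Vadar loci. The table does not pair identifiers with gene names or functions, and no genome or annotation was used here. Non-Vadar loci are described without their identifiers. The gene lists fixed in advance (26 lists, among them anthocyanin synthesis, potassium transport, sulfate assimilation, sugar transport, cell wall softening, hormones, and markers of seed, green tissue, floral and vascular tissue) could therefore not be matched to any gene, and none was tested. Positions in the genome are not given for the same reason.

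Library totals ran from 15655016 to 18424967 counts. Genes were kept by edgeR's filterByExpr with its default minimum count of 10 and minimum total of 15, which left 25728 genes (19981 Vadar genes and 5747 non-Vadar loci) holding 99.8% of the counts of each library. Library-scaled abundances (CPM, cpm() in edgeR) were computed from totals scaled by TMM factors. The main test was edgeR 4.0.16's quasi-likelihood F test in R 4.3.3, fitted to all 9 libraries with 1 term per group and no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Every adjusted p below comes from that fit unless another tool is named. The standard error of a log2 fold change is the fold change divided by the square root of its F value. "Rose" and "fell" refer to genes past the threshold. A group in which a gene has 0 counts in every library was given a floor of 3 counts over the group when a fold was formed against it. Where a group held 1 to 3 counts, the ratio of abundances is given with its 95% interval (exact Clopper-Pearson on the division of the counts). Intervals and floors cover counting error only.

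All 3 pairwise comparisons and a joint test over the groups were made. Distances between libraries were measured on log2 CPM with a prior count of 2, and the share of variance between groups was set, one-sided, against all 280 ways to part the 9 libraries into 3 groups of 3. Single measures per library were compared by exact two-sided permutation tests. Since the 2 potassium groups share the water libraries, 20 data sets with no change in any group were simulated from the water means, the observed dispersions and the real library sizes, and analysed in the same way. Fixed before the data were examined were the groups, the main test, its alternatives and the rule for the genes named: in each comparison the 2 that rose and the 2 that fell most, among genes past the threshold with a mean log2 CPM of at least 2 and groups that do not overlap. Abundance classes by mean CPM over all 9 libraries, the comparison of Vadar genes with non-Vadar loci, the counts of genes at 0 and the measures of library composition were chosen after the data had been seen.

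Alternatives covered 3 other scalings, 3 other filters, DESeq2 1.42.0, limma 3.58.1 with voom weights, fits to 2 groups only, the replicate number as a block, other thresholds and each library left out in turn.

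The test was tried on simulated data with 25728 genes, once per comparison, of which 50 were changed 1.5-fold, 50 2-fold and 100 4-fold. For potassium at flowering against water it called 44% of genes changed 1.5-fold, 76% of those changed 2-fold and 90% of those changed 4-fold, and 3.85% of its calls were unchanged genes. In the simulation of potassium at young fruit against water, 9.94% of calls were unchanged genes. In that of the 2 timings 9.41% were, and both exceed the nominal 5% set by the threshold. Far fewer genes were changed in these simulations than were called in the data, and the adjusted p depends on that share. The percentages therefore do not give the recovery or the false calls of the main test.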

Results

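Transcript abundance was measured by RNA sequencing in rabbiteye blueberry fruit after potassium sulfate had been given at flowering or at the young fruit stage, and in fruit of plants given water. The title of the series gives anthocyanin production, the red to blue fruit pigments, under potassium as its subject. Each of the 3 groups held 3 libraries. Total counts were 15655016, 18424967 and 15704122 in water, 16809986, 15988279 and 15923402 after potassium at flowering, and 16422335, 15979510 and 16812796 after potassium at young fruit. Genes are named by identifier only, since the table gives no gene names.

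The libraries fell into their 3 groups. Water stood apart from both potassium groups along the first principal component, which carried 62.8% of the variance, and the 2 timings parted along the second, with 13.3%. Between-group differences made up 75.9% of the variance of log2 CPM, more than under any other of the 280 partitions (next highest 68.2%, one-sided exact permutation p = 0.00357, the smallest that these partitions allow). Spearman correlations across genes lay between 0.985 and 0.988 within groups, between 0.973 and 0.975 for the 2 timings, and between 0.926 and 0.932 for water against either potassium group. No pair of replicates looked like a repeated deposit: chi-square per degree of freedom ranged from 2.62 to 5.79 within groups, above the value near 1 that sampling alone gives. Whether counts that are estimates could raise it for a true repeat was not tested.

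**Figure D1:**
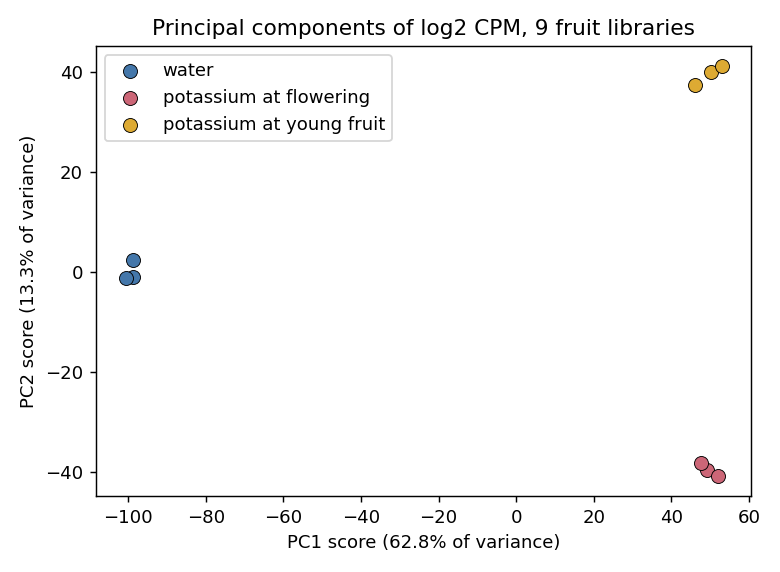
Scores of the 9 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, 1 point per library, coloured by group. Water lies apart on the first component and the 2 potassium timings part on the second.

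Fewer genes were detected in each potassium library than in any water library. At an equal total of counts, 34038 ± 89.8 genes (SD, n = 3) were detected in water, 32939 ± 135 after potassium at flowering and 33116 ± 145 after potassium at young fruit. The unthinned numbers were 34139 ± 254, 33011 ± 133 and 33204 ± 122. The single most abundant gene of each library took 0.929 ± 0.104% of the counts in water, 1.65 ± 0.08% after flowering-stage and 1.43 ± 0.05% after young-fruit-stage potassium, and the 10 most abundant took 5.43 ± 0.02%, 6.23 ± 0.13% and 6.06 ± 0.10%. Water against the 6 potassium libraries gave p = 0.0119 for each of these measures in a two-sided exact permutation test (adjusted p = 0.0179 over 6 measures), the smallest that 3 against 6 allows. For the share of the 100 most abundant genes (18.9, 19.7 and 19.0%) and of non-Vadar loci (10.0, 9.76 and 9.63%) the exact permutation p was 0.0952 and 0.0595 (adjusted p = 0.0952 and 0.0714). With 3 libraries against 3, p cannot go below 0.10.

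Whether potassium at flowering altered the fruit transcriptome was addressed by the first comparison. Of 25728 genes tested, 6263 rose and 6272 fell relative to water, 48.7% of all genes. The median change among them was 0.70 on the log2 scale in either direction. At least 2-fold changes were seen in 1564 genes that rose and 2918 that fell, and at least 4-fold changes in 569 and 1074. Among abundant genes more rose than fell, and among scarce genes more fell than rose. Classes were set by the mean over all 9 libraries, so a gene's own change helped to place it. How much of the pattern comes from that was not tested. Among the 2058 genes with a mean over 100 CPM, 58.0% rose and 21.9% fell, with a median log2 fold change of 0.22. Among the 10276 genes at 1 to 10 CPM, 12.6% rose and 26.8% fell, with a median of -0.17, and among the 3788 below 1 CPM 7.71% rose and 18.0% fell. Of the 100 most abundant genes, 62 rose and 29 fell. These directions held under all 4 scalings run, none of which takes a gene's own change out of its class. By contrast, the class at 10 to 100 CPM (36.3% rose, 24.9% fell) turned under scaling by library size alone (26.7% rose, 32.3% fell).

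The genes that rose most were Vadar_g30827.v1.2 and Vadar_g30825.v1.2. Vadar_g30827.v1.2 had 1 count over the 3 water libraries and 16.9 ± 1.52 CPM (SD, n = 3) after potassium, a ratio of 882 (95% interval 158 to 34882, edgeR adjusted p = 5.26e-16). Vadar_g30825.v1.2 had 2 counts in water, both in replicate 1, and 28.2 ± 3.32 CPM after potassium, a ratio of 738 (204 to 6102, edgeR adjusted p = 3.70e-17). These sizes rest on 1 water library each: the log2 fold change moved from 9.30 to 11.08 without water replicate 2 for the first gene and from 9.26 to 11.85 without water replicate 1 for the second. Their identifiers are 2 numbers apart, and whether counting divided reads between them is not known. The genes that fell most, Vadar_g42218.v1.2 and Vadar_g6849.v1.2, had 38.5 ± 9.10 and 15.4 ± 1.87 CPM in water and 0 counts in all 3 libraries of potassium at flowering. They were at least 609-fold and 243-fold lower (edgeR adjusted p = 3.50e-16 and 1.28e-14). Scaling by library size alone moved the median log2 fold change of all genes from -0.02 to -0.13 and the split to 4846 that rose and 7719 that fell. The classes at 10 to 100 and over 100 CPM lay 0.10 and 0.24 above the median of all genes, a distance that a change of scaling leaves nearly as it is.

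Potassium at young fruit gave a change of similar extent. Relative to water 6582 genes rose and 6624 fell, 51.3% of those tested, with a median change of 0.74 on the log2 scale. At least 2-fold, 1864 rose and 3093 fell, and at least 4-fold 641 and 983. The division by abundance was similar: of the 2058 genes over 100 CPM 1131 rose and 504 fell, while of those at 1 to 10 CPM 14.6% rose and 27.7% fell and of those below 1 CPM 9.27% rose and 17.9% fell. Among the 100 most abundant genes 60 rose and 31 fell. The class at 10 to 100 CPM (3601 rose, 2591 fell) again turned under library size scaling (2712 rose, 3347 fell).

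**Figure D2:**
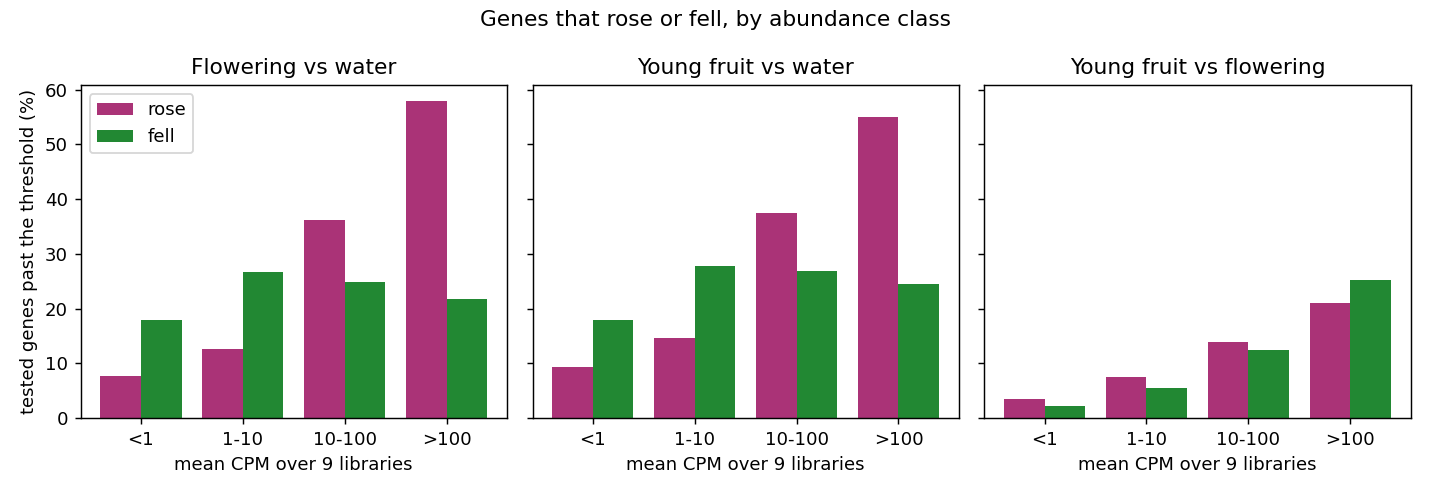
Percent of tested genes (y axis) that rose or fell in each comparison, by mean CPM over the 9 libraries (x axis). Against water, 1193 genes over 100 CPM rose at flowering and 1131 at young fruit, and falls outnumber rises below 10 CPM. At 10 to 100 CPM the order turns under library size scaling. A gene's own change enters the mean CPM that sets its class.

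The genes that rose most after potassium at young fruit were a non-Vadar locus and Vadar_g26641.v1.2. The locus had 2 counts over the water libraries and 18.6 ± 1.63 CPM after potassium, a ratio of 487 (95% interval 134 to 4029, edgeR adjusted p = 2.82e-16). Vadar_g26641.v1.2 went from 3.48 ± 0.15 to 543 ± 66.2 CPM (log2 fold change 7.28 ± 0.10, SE, edgeR adjusted p = 2.28e-24), and stood at 144 ± 6.47 CPM after potassium at flowering. The genes that fell most were Vadar_g30930.v1.2, from 42.6 ± 1.8 to 0.21 ± 0.18 CPM (log2 fold change -7.61 ± 0.24), and Vadar_g41665.v1.2, from 159 ± 11 to 1.00 ± 0.27 CPM (-7.30 ± 0.12). Their edgeR adjusted p values were 3.07e-18 and 5.12e-23. Both were also low after potassium at flowering, at 0.21 ± 0.08 and 1.2 ± 0.20 CPM. Library size scaling moved the median of all genes from -0.02 to -0.14 and the split to 5132 that rose and 8190 that fell.

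**Figure D3:**
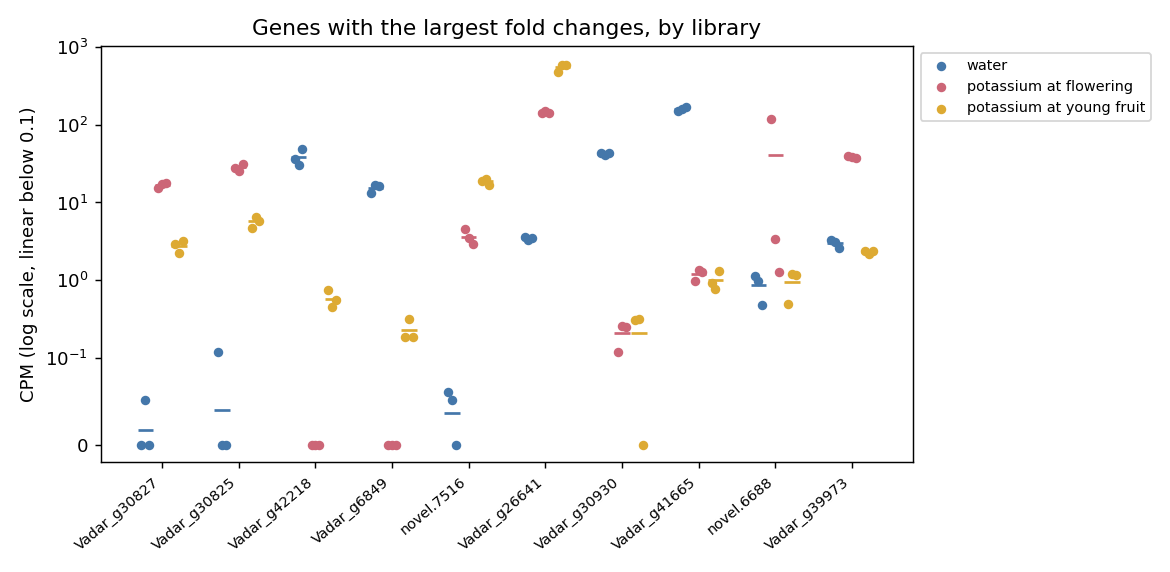
CPM (y axis, log scale, linear below 0.1) of the named genes in each of the 9 libraries, with points for libraries and lines for group means. Vadar_g42218.v1.2 and Vadar_g6849.v1.2 lie at 0 in all 3 libraries of potassium at flowering, and the non-Vadar locus that fell most between the timings is high in 1 of them.

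Both timings moved largely the same genes in the same direction. Of the genes tested, 4996 rose and 4889 fell at both timings, and 181 changed in opposite directions. Lists drawn independently would share 1602 that rose and 1615 that fell. In 20 simulations of unchanged groups sharing the water libraries, a mean of 0.1 genes rose and 0 fell at both timings. With no gene changed almost none is called, so these 2 counts cannot show how much overlap shared controls add. Log2 fold changes of the 2 timings correlated across genes at r = 0.86, against 0.50 ± 0.01 (SD of 20 simulations) from the shared water libraries alone. Without any change the shared libraries set r near 0.50, so that value is not a share of the 0.86. Their covariance was 1.01 against 0.033 simulated, a difference of 0.98. Genes are not independent replicates. The 3 water libraries were not split between the 2 comparisons, so part of the overlap may come from the shared controls.

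**Figure D4:**
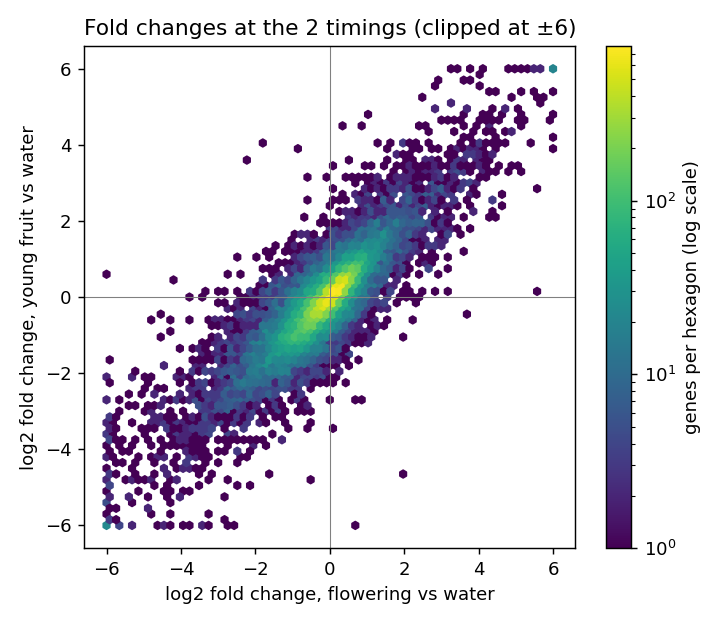
Log2 fold change against water of each tested gene at flowering (x axis) and at young fruit (y axis), clipped at 6, with colour for the number of genes per hexagon on a log scale. Most genes lie along the diagonal (r = 0.86).

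The effect of timing was tested directly between the 2 potassium groups. Relative to potassium at flowering, 2676 genes were higher and 2377 lower after potassium at young fruit, 19.6% of those tested, with a median change of 0.50 on the log2 scale. Under upper quartile scaling the order turned, with 2534 higher and 2587 lower. Differences of at least 2-fold were fewer and mostly upward, in 753 genes that were higher and 388 that were lower. Among genes that rose at both timings, 856 were higher after young-fruit-stage and 515 after flowering-stage potassium. Among those that fell at both, 599 were lower after young-fruit-stage and 462 after flowering-stage potassium. Of the 181 genes with opposite directions, 121 fell at flowering and rose at young fruit and 60 did the reverse.

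By the fixed rule the largest differences in timing included 2 genes near the floor. Vadar_g42218.v1.2 had 28 and Vadar_g6849.v1.2 11 counts over the young fruit libraries against 0 at flowering, at least 9.27-fold and 3.66-fold higher (edgeR adjusted p = 0.000374 and 0.00385). Both remained far below water, and both were under the count filter when only the potassium groups entered the fit. Vadar_g39973.v1.2 was lower at young fruit, 2.32 ± 0.12 against 38.4 ± 0.88 CPM (log2 fold change -4.04 ± 0.13, edgeR adjusted p = 2.04e-16), and near its water level of 3.01 ± 0.36 CPM. A non-Vadar locus had a log2 fold change of -5.39 ± 1.08 (edgeR adjusted p = 0.000761) that rests on 1 library: potassium at flowering replicate 1 held 1912 counts against 52 and 20 in its replicates. Without it the value was -1.26 (edgeR adjusted p = 0.085).

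Over the 3 groups together, 14800 of 25728 genes (57.5%) differed in edgeR's joint test. In flowering-stage potassium against water 52.5% of Vadar genes and 35.8% of non-Vadar loci changed, and in young-fruit-stage potassium against water 54.9% and 39.1%. Non-Vadar loci were scarcer, with a median of 1.97 CPM against 11.3 CPM. Among Vadar genes there were 2422 falls and 1013 rises of at least 2-fold at flowering, and 2517 and 1278 at young fruit. Among non-Vadar loci there were 496 falls and 551 rises at flowering, and 576 and 586 at young fruit.

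A small set of genes was detected in one group and at 0 in another. With at least 10 counts in each water library, 41 genes had 0 counts in every library of potassium at flowering and 27 in every library of potassium at young fruit, of which 10 were at 0 in both. In reverse, 11 genes were at 0 in water with at least 10 counts in each library of potassium at flowering, 11 likewise at young fruit, and 6 in both. Between the timings there was 1 such gene in each direction, and 1 to 3 with any 1 library left out (3 in each without flowering replicate 2). A count of 0 limits expression only to under 3 counts over the group, for counting error alone. These numbers grow when fewer libraries must be at 0: without flowering replicate 1 the 41 became 64, without young fruit replicate 1 the 27 became 48, and without any 1 water library the 2 counts of 11 became 17 to 21 and the 6 became 9 to 11.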

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

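The test of repeated libraries was chosen after the spread between replicates had been seen, and the other tests in this part before their results were seen. The 2 results below stand out because the change against the same water libraries differed between the timings of potassium, by the direct test between the potassium groups.

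In that test 5053 genes differed between flowering and young fruit. Of the 5053, 165 lower and 154 higher at young fruit passed the threshold against water at neither timing. The 5053 also held the 181 genes past the threshold in opposite directions at the 2 timings. For these 181 a difference between timings follows from how they were selected.

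The number of genes that changed against water, 12535 at flowering and 13206 at young fruit, may have a technical part. Library depth is argued against by the library totals, which ran from 15655016 to 18424967 counts and overlapped between groups. Thinning every library to the smallest total left 12475 genes at flowering. That thinning removed few counts except from water replicate 2, so it adds little. Repeated sequencing of 1 library under several replicate numbers is argued against by the spread within groups. The median chi-square per degree of freedom was 3.20, well over the value near 1 that plain sampling of counts would give. The labels name no batch, so a batch that followed the groups and the potassium sulfate treatment cannot be told apart. Potassium and sulfate were given together, so they cannot be told apart either. All fruit was picked 90 days after flowering, so the timing of the treatment and the time from treatment to picking cannot be told apart. Whether replicates came from separate plants is also open. The biological explanation, the potassium sulfate treatment, was tested only through these same libraries.

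Other divisions of the libraries were counted beside each result. With 3 libraries against 3 there are 10 divisions, and the share that reaches the real value cannot fall under 0.10. The real one, 1 of 10, gave 12535 genes at flowering against water (highest other 0), 13206 at young fruit against water (highest other 0) and 5053 between the timings (highest other 1). For changes of at least 2-fold the real divisions gave 4482, 4957 and 1141 genes and the highest others 0, 0 and 1. For the 3 groups, 100 divisions were counted, the real one and others drawn at random, so 1 of 100 is the fewest possible. In the joint test only the real one reached 14800 genes (highest other 9819). For genes changed the same way at both timings, 1 of 100 reached 9885 (highest other 243). That last count depends on which group of a drawn division was labelled water, which was set at random. For the joint test a random division of the libraries is argued against, as far as the divisions drawn can show. For genes changed the same way the count cannot decide, because of that random label. Chance differences between the plants of the groups are not covered.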

How the results depend on the processing

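The alternatives named here were fixed before the data were examined, except thinning, the fit to Vadar genes alone and the other count minimums for genes at 0, which were chosen after seeing the data. For the counts of changed genes and the distance between libraries, 165 values stayed within 1.5 times or on the same side of the threshold, and 7 did not. The 165 include the fit without any filter, described below. For counts of genes only totals were compared, so a shift between rises and falls did not register. Under upper quartile scaling the balance between timings turned, to 2534 higher and 2587 lower at young fruit. Requiring a mean of at least 50 counts tested fewer genes and left 2254 changes of at least 2-fold for flowering against water, 2524 for young fruit against water and 558 between timings. Testing against a 1.5-fold change, a stricter null, left 4476, 4992 and 721 genes. An adjusted p under 0.01, a stricter threshold, left 3159 genes between timings. DESeq2 called 11685, 12345 and 4383 genes, of which 11156, 11771 and 4355 were also edgeR calls. Leaving out each library in turn gave 11449 to 12895, 12098 to 13376 and 3875 to 5362 genes, and 8996 to 9626 shared between timings. Without any filter the quasi-likelihood prior degrees of freedom were infinite (16.6 with the filter used), so each gene's own spread was not used, and its 13321, 13926 and 5343 genes and its p-values are no evidence of stability. The replicate number as a block gave 12699, 13328 and 5358 genes and changed no call on a named gene. Deviations of libraries sharing a number correlated between -0.038 and 0.046, and 3 of 9 libraries correlated best with their own number, so the numbers were not taken to pair libraries. Of the named genes, the non-Vadar locus that fell between timings lost its call under limma-voom (adjusted p = 0.257), with sample weights (0.267) and without flowering replicate 1 (edgeR, 0.085). DESeq2 gave it no adjusted p, and over the other edgeR fits, the unfiltered one left aside, its adjusted p ran from 1.53e-05 to 0.0065. The prior degrees of freedom were read only for the filter settings, so those of the remaining fits are not known. Vadar_g42218.v1.2 and Vadar_g6849.v1.2 had no test between timings with only those groups in the fit, being under the count filter there. Minimum counts of 5 and 20 moved the genes at 0 at flowering to 96 and 21, at young fruit to 76 and 12, and in water to 33 and 5 (against flowering) and 28 and 6 (against young fruit). The 10 at 0 at both timings became 34 and 5, the 6 in water 14 and 1, and the 1 between timings 3 and 0 at flowering and 6 and 0 at young fruit. Gene list alternatives were not run, since no gene could be named. In simulation 44% of 1.5-fold changes at flowering were recovered. Whether depth, replicate number, spread or the small share of changed genes in the simulation limits this was not tested.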

Other observations

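The comparison of non-Vadar loci with matched lists, the share without equal genes and the size of the falls were chosen after the results had been seen; bounds for the other tests in this part were set before their results were seen, on patterns already noticed in the data.

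Among the 23185 genes with at least 10 counts in each water library, 239 lay at or under 1/16 of their water level after potassium at flowering and 174 after potassium at young fruit. Of these, 41 and 27 had no counts. A further 128 and 103 of the 23185 genes had 1 to 5 counts over the group. Of the non-Vadar loci 35.8% passed the threshold at flowering, against 39.3% (95% range 38.3 to 40.3%) in 10000 random lists matched on mean expression. At young fruit 39.1% did, against 41.8% (40.8 to 42.9%). The lists were drawn from all tested genes, non-Vadar loci included, so they understate any gap to Vadar genes of equal abundance. Between timings the 13.5% lay inside the matched range of 13.0 to 14.5%.

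The excess of falls over rises among 2-fold changes against water may be technical. Scaling by a few abundant genes is argued against, since removing the 100 most abundant genes moved the share of falls among 2-fold calls at flowering from 71.5 to 70.2% with library size scaling and from 65.1 to 65.4% with TMM. Reads spread evenly over all genes in the water libraries are argued against. Of 5906 genes with at most 3 counts over the young fruit libraries, 57.2% were higher in water than at flowering and 33.9% were lower. The 57.2% lies under the 60% set as the limit. Without equal genes 62.8% were higher, over that limit. The excess in water had a median of 0.0193 and a mean of 0.0579 CPM where the smallest 2-fold fall was 0.399 CPM. At young fruit these were 0.0187, 0.0720 and 0.191 CPM, with 56.6% higher, and 60.7% without equal genes. Lower depth cannot account for the fewer genes detected after potassium, with 702 between the lowest water and the highest potassium library after thinning. Noise of genes with low counts stays open, since its test cannot decide. Among genes of at least 10 CPM 52.9% of 2-fold calls at flowering were falls (49.5% at young fruit). Both lie within the 55% set beforehand as its mark, although 65.0% were falls at flowering among genes averaging at least 50 counts. The 52.9% mixes 57.3% at 10 to 100 CPM with 35.4% over 100 CPM. The mark therefore cannot tell noise from a share of falls that varies with abundance. The share was 69.62% at 1 to 10 CPM and 69.96% under 1 CPM at flowering. At young fruit these were 68.01% and 65.99%. RNA quality, GC content, gene length and a background uneven between genes were not tested, so no biological reading of the excess is offered.

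Vadar genes with consecutive identifier numbers changed alike, which may come from reads shared between adjacent near-identical copies. Across 10962 pairs of genes, which are not independent replicates, the Spearman correlation of log2 fold changes was 0.13 at flowering, 0.13 at young fruit and 0.088 between timings (one-sided permutation p = 1e-05 in each of these 3 tests, the smallest that 100000 permutations can give). Adjusted for abundance it was 0.13, 0.12 and 0.089. At flowering it was 0.045 for numbers 2 to 5 apart and 0.0066 for numbers 6 to 20 apart, the short range that shared reads would give. Shared regulation of neighbouring genes would give it too and was not tested, and that numbers follow genome order is an assumption.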
